A study of Mus musculus with 7 samples.

How the data were processed

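ATAC-seq libraries of sorted CD45.2+ Foxp3-YFP+ Treg cells from spleens of mixed bone marrow chimeras were compared, 4 WT and 3 Opa1 KO, per the labels. Nuclei were treated with transposase and the DNA was amplified with barcoded primers, per the labels' protocols. The authors deposited 1 table of whole-number counts per peak, not normalized, with 7 library columns over 1 set of 50213 intervals that do not overlap. Per the submitters' processing notes, the tools used were Trimmomatic 0.36, BWA 0.7.16, Picard 2.9.4, SAMtools 1.9, MACS2 2.1.1 and bedtools 2.25.0 with the mm10 build. How they were set, how peaks were merged across libraries, and whether reads were shifted for the transposase offset are not given in the sources used here. Peak edges can move by a few bases with such a shift, and a peak set called on pooled reads favours sites open in the deepest libraries. Whether interval starts count from 0 or 1 is not stated, so positions are given as deposited.

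Between 78.0% and 86.3% of the deposited counts per library were even, which is what counting both mates of each read pair gives, so counts overstate the number of fragments. Library totals in peaks ran from 1534394 to 3384325, and the median count per peak from 14 to 30. PCR reads without molecular identifiers are not independent molecules, so the floor of 3 read pairs, 6 counts, used for a peak without counts covers counting error only. Counts of each pair of libraries, halved, were compared by chi-square. WT replicates 2 and 3 differed by no more than sampling noise over 36418 peaks with a mean count of at least 10 (chi-square p = 0.11). Over 11332 peaks with a mean count of at least 50 the chi-square p was 0.038, the weakest difference of any pair within a genotype. They were counted as 1 sample in every mean ± SD and kept as separate libraries in the tests, since the design had been fixed.

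Peaks were matched to protein-coding genes of a GRCm38 gene table, the assembly that mm10 names: the gene a peak touched (32474 peaks), or otherwise the gene with the nearest end within 100 kb (14995 peaks). No gene was assigned to 2744 peaks. The table gives no strand and no exons, so transcript starts, promoters, exons and introns were not assigned, and the planned promoter share was replaced by peaks within 1 kb of either end of a gene (23.5% of peaks), a choice made after the table had been seen. Assignment by distance does not show which gene a site acts on. The names of the interferon, lysosome and core Treg lists stood for 31, 63 and 18 protein-coding genes of the table, since some were second names of one gene, pseudogenes or not in it, and each name of the other lists matched its own gene.

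The main test was edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 on all 7 libraries with genotype as the only term, after filterByExpr (minimum count 10, total 15), which kept 38041 peaks and removed 12172, with TMM factors (0.985 to 1.013) and Benjamini-Hochberg adjustment at 0.05. Adjusted p values are from this test unless another is named. CPM values are counts scaled to a common total with the TMM factors. The common biological coefficient of variation was 0.157. It was estimated on counts that hold both mates of a pair, so it includes sampling noise of the pairs. With counts halved, libraries of a genotype differed little beyond sampling noise (chi-square per degree of freedom 1.004 to 1.08). The 18 gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2, over lists with at least 10 peaks, with an estimated correlation and with fry beside it. The tests, lists, alternatives and the rule for named peaks were fixed before the data were examined, apart from the promoter share and the assignment of genes. Assignment had been planned by the nearest transcript start within 100 kb, which the gene table does not give. The list tests and the named peaks rest on the replacement, overlap or the nearest gene end. The rule took each tested Opa1 peak, the 10 higher and 10 lower called peaks with the smallest adjusted p whose groups did not overlap (1 per gene), up to 3 called genes per list or else its peak with the smallest p, and the peak with the highest mean count of 11 genes of Treg biology. The Atm, Trim30c, Atp6v1b2 and Hopx peaks and the lower peak on the scaffold JH584304.1 fall outside that rule and were chosen after their values were seen. Shares per library were compared by exact permutation over the 35 splits into 4 and 3, and other tests used SciPy 1.17.1, with pandas 2.3.3, NumPy 2.4.6 and Python 3.11.15, and plots matplotlib 3.10.9.

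The procedure was tested on simulated counts drawn from the real means, library sizes and fitted dispersions for KO against WT. Of the peaks changed 1.5-fold it called 10.4%, of those changed 2-fold 49.3% and of those changed 4-fold 83.3%, with 1 false call among 96 over 35872 peaks. A simulated Treg list raised 1.3-fold was called (adjusted p = 4.9e-22) and no other list was.

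Alternatives were DESeq2 size factors, total counts alone and loess offsets; no count filter and a mean count of at least 20; DESeq2 1.42.0 and limma-voom; the replicate number as a block; each library left out; thresholds of 0.01 and 0.1; and, for lists, fry, an estimated correlation and assignment within 20 kb. Added after the data had been seen were WT replicates 2 and 3 summed, counts halved, halved counts thinned to 770630 per library, chromosome 16 left out, gene-end peaks for the lists, counts of all peaks of a gene summed, and the splits into 3 and 3 with WT replicates 2 and 3 summed. Motif tests and GC corrections need the genome sequence, which was not used here.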

Results

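Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in regulatory T cells (Treg cells) of the mouse spleen. The cells came from mixed bone marrow chimeras, mice rebuilt with a 1:1 mix of CD45.1+ marrow and CD45.2+ marrow. The CD45.2+ marrow was either Foxp3-Cre (wild type, WT) or Foxp3-Cre with floxed Opa1, in which Cre deletes Opa1 in cells that express Foxp3 (Opa1 KO). Cells positive for CD45.2, CD4 and the Foxp3-YFP reporter and negative for CD45.1 were sorted. There were 4 WT and 3 Opa1 KO chimeras, and each gave 1 library. The table held counts at 50213 peaks with a median width of 319 bp. The total count in peaks was 2134586, 1534394, 1706750 and 1951574 in WT replicates 1 to 4. It was 3384325, 1658436 and 1948041 in KO replicates 1 to 3, so KO replicate 1 was the deepest library. The counts of WT replicates 2 and 3 differed by no more than sampling noise (chi-square per degree of freedom 1.009, p = 0.11 over 36418 peaks). Every other pair within a genotype differed at that test, WT replicates 3 and 4 the least (1.022, chi-square p = 0.0014). WT replicates 2 and 3 had the lowest WT totals, and the test has less power at low depth. Over the 11332 most abundant peaks they did differ (chi-square p = 0.038), and the labels give 4 mice, so it is not settled whether they are separate samples. As a precaution their mean was counted as 1 sample, and each mean below has n = 3 for both genotypes, while the tests kept the 7 libraries. Averaging replicates 2 and 3 can make a WT SD narrower than the spread of the 4 WT libraries. Coordinates are those of mm10.

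The comparison asked how loss of Opa1, a GTPase of the inner mitochondrial membrane that acts in membrane fusion and cristae shape, altered accessible chromatin in Treg cells. The series concerns exchange between mitochondria and lysosomes during Treg differentiation. The Opa1 gene lies on chromosome 16 from 29579281 to 29663127. Its tested peak, from 29579139 to 29579524, covered the end of the gene at its lower coordinate. It had 36.8 ± 1.17 CPM, counts scaled to a common library total, in WT (SD, n = 3) and 35.0 ± 6.93 in KO (SD, n = 3). The log2 fold change was -0.06 with a standard error of 0.19 (adjusted p = 0.955). Which exons were deleted is not given in the sources used here. A peak outside them says nothing about the deletion, so this peak does not check the genotype labels.

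Few peaks passed the threshold. Of 38041 peaks tested, 33 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 18 higher and 15 lower in KO. This is no count of all changed sites. An unadjusted p under 0.05 was reached by 3603 peaks, where 1902 are expected without any change. The groups did not overlap at 9.36% of the tested peaks, where chance gives 5.71%. On simulated counts the test recovered 10.4% of the peaks changed 1.5-fold, so smaller changes at further sites are not excluded. Outside chromosome 16, the most clearly lower peak lay inside Mpp7, which encodes a scaffold protein of cell polarity. The next lay near Bhlhe40, a transcription factor of activated and effector T cells. The higher peaks included sites near Esrp1, a splicing regulator of epithelial cells, and in Fbxl17, an F-box protein of ubiquitin ligases. Others lay near Galnt6, an enzyme of O-linked glycosylation, and at an end of Atp6v1d, a subunit of the proton pump that acidifies lysosomes. Chromosome 16 held 13 of the 33 called peaks. The split of the calls by direction moved with the scaling, to 14 higher and 23 lower with total counts as the only scaling and to 12 higher and 24 lower with loess offsets. The number called moved with other settings at this threshold, from 13 with the replicate number as a block to 82 with counts halved.

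**Figure D1:**
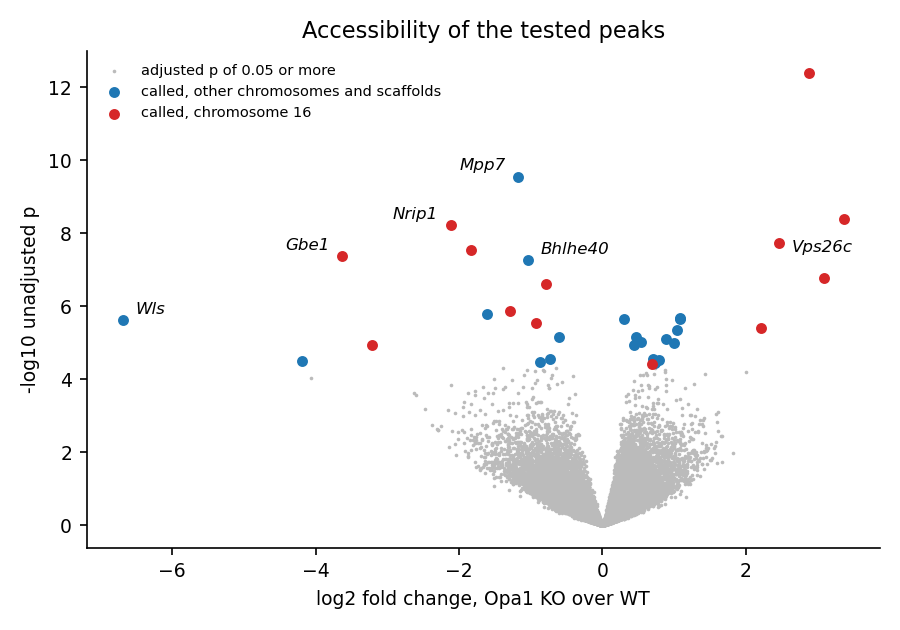
Log2 fold change of accessibility, Opa1 KO over WT (x axis), against -log10 of the unadjusted p of edgeR's quasi-likelihood test (y axis), for 38041 tested peaks. Grey points had an adjusted p of 0.05 or more; the 13 called peaks on chromosome 16 are red and the other 20 blue, and the Wls peak, with no count in KO, has a fitted fold that is no measured size.

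The Mpp7 peak (chromosome 18, 7608818 to 7609449, within the gene) had 73.9 ± 6.45 CPM in WT and 32.8 ± 2.96 in KO, a log2 fold change of -1.18 (SE 0.16, adjusted p = 5.32e-06). The Bhlhe40 peak (chromosome 6, 108688339 to 108688786) lay 21414 bp outside the gene. It fell from 63.0 ± 3.89 to 30.4 ± 1.16 CPM (log2 fold change -1.03, SE 0.17, adjusted p = 0.000265). WT replicates 2 and 3, averaged for this SD, had the highest and lowest WT values here, 69.05 and 51.79 CPM. The single WT libraries therefore spread wider than the SD shows. A peak 11440 bp from Rab10, a small GTPase of vesicle traffic (chromosome 12, 3235143 to 3235988), had 111 ± 10.1 in WT and 72.9 ± 11.9 in KO (log2 fold change -0.60, adjusted p = 0.0127). A peak within Wls, the carrier of secreted Wnt proteins (chromosome 3, 159869713 to 159870037), had 6.32 ± 2.86 CPM in WT and no count in any KO library. A floor of 3 read pairs (6 counts, since both mates are counted) over the KO group is 0.898 CPM. The WT mean of this peak was 7-fold that floor (adjusted p = 0.00575). This fold leaves out the error of the WT mean, whose single libraries ran from 3.16 to 8.72 CPM.

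Among the higher peaks outside chromosome 16, the peak 17230 bp from Esrp1 (chromosome 4, 11404013 to 11404389) rose from 19.3 ± 4.63 to 43.9 ± 4.87 CPM (log2 fold change 1.09, SE 0.21, adjusted p = 0.00562). The Fbxl17 peak (chromosome 17, 63362115 to 63362557, within the gene) rose from 20.7 ± 3.21 to 42.4 ± 7.22, and the peak 3248 bp from Galnt6 (chromosome 15, 100732624 to 100733075) from 20.3 ± 1.63 to 42.1 ± 4.81. Their log2 fold changes were 1.08 (adjusted p = 0.00562) and 1.04 (adjusted p = 0.00892). At the Galnt6 peak the averaged WT replicates 2 and 3 had 16.25 and 26.5 CPM, the lowest and highest WT values, so its WT SD is narrow too. A peak on chromosome 18 from 79256982 to 79257603 with no protein-coding gene within 100 kb rose from 142 ± 12.1 to 202 ± 18.3 (log2 fold change 0.46, adjusted p = 0.0127). On the unplaced scaffold JH584304.1 the peak from 58657 to 60126 rose from 932 ± 16.4 to 1147 ± 87.8 (log2 fold change 0.30, adjusted p = 0.00562).

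**Figure D2:**
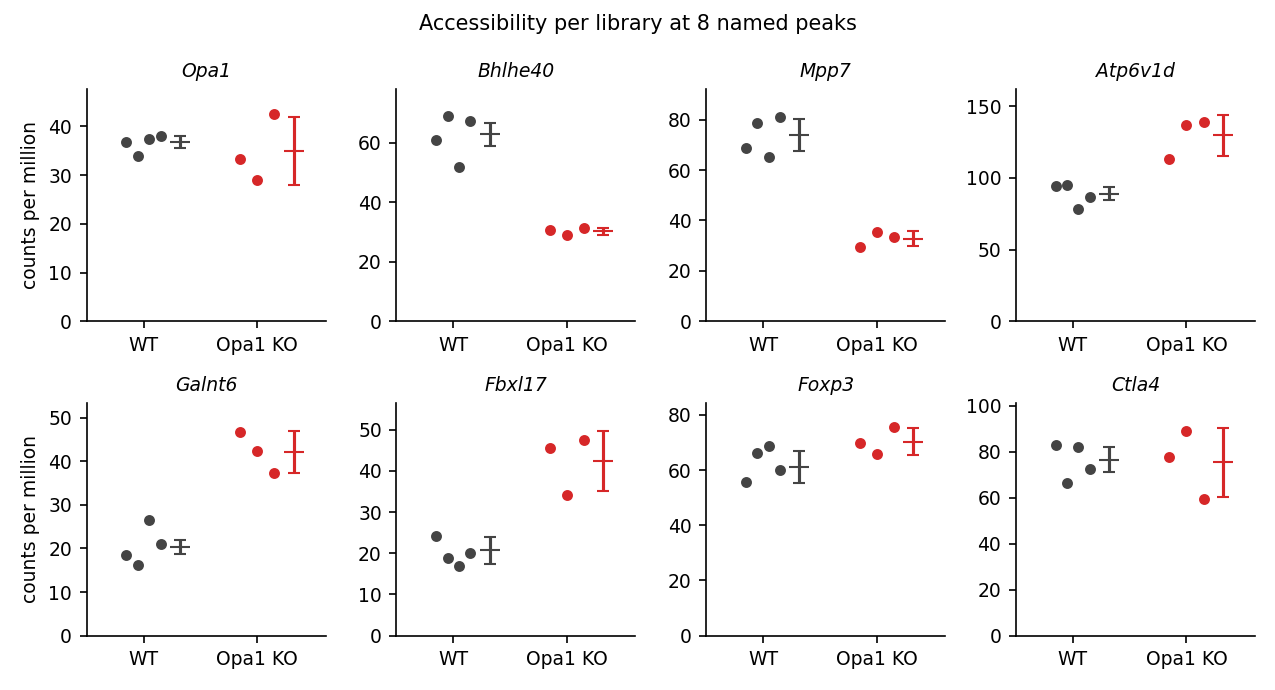
CPM (y axis, from 0) at 8 named peaks. Each point is 1 library (4 WT, 3 Opa1 KO) and the bars are mean ± SD with WT replicates 2 and 3 counted as 1 sample; the Bhlhe40 peak lay at 63.0 ± 3.89 in WT and 30.4 ± 1.16 in KO, while the groups overlap at the Opa1, Foxp3 and Ctla4 peaks.

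On chromosome 16, 6 peaks were higher and 7 lower. Of the higher ones, 3 lay within 1.5 kb in a stretch with no protein-coding gene within 100 kb. The strongest, from 77644379 to 77644717, rose from 4.36 ± 1.87 to 30.4 ± 3.59 CPM (log2 fold change 2.89, SE 0.32, adjusted p = 1.59e-08). Its neighbours from 77645009 to 77645315 and from 77643867 to 77644139 had log2 fold changes of 3.37 (adjusted p = 5.34e-05) and 2.21 (adjusted p = 0.00857). A peak in the noncoding gene Mir99ahg (77499862 to 77500243) had a log2 fold change of 3.09. One within Vps26c, an endosomal sorting protein (94510036 to 94510367), had a log2 fold change of 2.47. A lower peak lay within Nrip1, a corepressor of nuclear receptors (76337478 to 76337793), and fell from 24.3 ± 1.63 to 5.50 ± 1.05 CPM (log2 fold change -2.11, adjusted p = 5.73e-05). Others lay within D16Ertd472e (78547406 to 78547732, log2 fold change -1.83) and within Gbe1, the glycogen branching enzyme (70331843 to 70332224, log2 fold change -3.63). Farther along were peaks 41371 bp from Bach1, a heme-regulated repressor (87657356 to 87657583, log2 fold change -3.21), and 32947 bp from Dscam, an adhesion protein (97204060 to 97204562, -0.93). An intergenic peak from 78200338 to 78200941 had a log2 fold change of -0.79. The adjusted p was 0.000726 for Mir99ahg, 0.000143 for Vps26c, 0.000182 for D16Ertd472e, 0.000235 for Gbe1, 0.017 for Bach1, 0.0065 for Dscam and 0.000948 for the intergenic peak. Drawing peaks at random would place 1.37 of the 33 on this chromosome (exact hypergeometric test, one-sided, p = 2.8e-10). The called peaks spanned 45389746 to 97204562. Of the 417 tested peaks within 10 Mb of Opa1, edgeR called 0 on all 7 libraries with filterByExpr and TMM, and 28 of them had an unadjusted p under 0.05. DESeq2 and limma-voom each called 1. So did edgeR with a mean count of at least 20, with WT replicates 2 and 3 summed, with counts halved, without WT replicate 3 and without KO replicate 3. The share of peaks with an unadjusted p under 0.01 was 0.96% within 10 Mb of Opa1, 16.9% between 70 and 80 Mb and 2.67% outside chromosome 16.

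**Figure D3:**
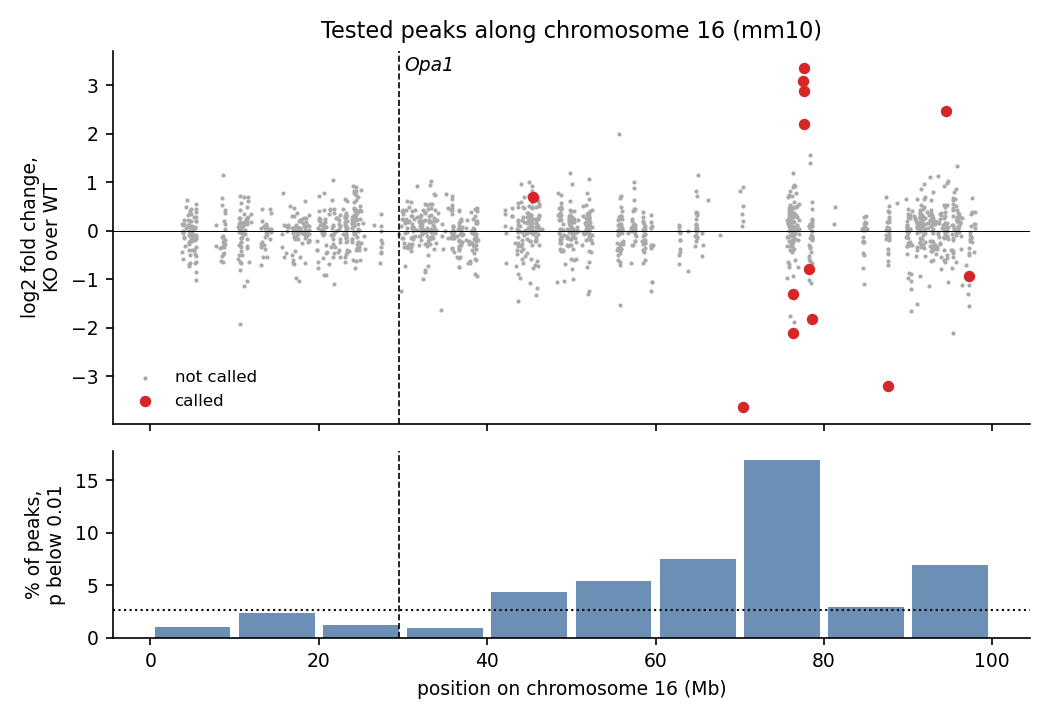
Top, log2 fold change (Opa1 KO over WT) of each tested peak along chromosome 16 (x axis, Mb, mm10), with the 13 called peaks in red and the Opa1 gene as a dashed line. Bottom, percent of peaks with an unadjusted p under 0.01 per 10 Mb, with the 2.67% found outside chromosome 16 as a dotted line; the share was 16.9% between 70 and 80 Mb.

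Of 21 named peaks that were called, 6 were called in every alternative that gave a value. They were the Mpp7, Bhlhe40, Nrip1 and D16Ertd472e peaks and those on chromosome 16 from 77644379 and 77645009. Another 14 lost the call in at least 1 fit with a library left out. The number of called peaks was 15 without KO replicate 1, 16 without KO replicate 3 and 18 without WT replicate 1. Rab10 lost its call without WT replicates 1 or 4 or KO replicates 1 or 3 (adjusted p from 0.0853 to 0.255). Esrp1 lost it without WT replicates 1 or 4 or KO replicate 3 (0.0571 to 0.0952), and Galnt6 without WT replicate 1 or KO replicate 1 (0.0843 to 0.174). Fbxl17 and Wls lost it without KO replicates 1 or 3 (0.0931 to 0.109 and 0.0663 to 0.112). The Wls peak passed the count filter in only 4 of the 7 fits with a library left out, and was called in 2 of them. The peak on chromosome 18 from 79256982 lost it without WT replicates 1 or 4 or KO replicates 2 or 3 (0.0554 to 0.184). The scaffold peak lost it without KO replicates 2 or 3 (0.0639 to 0.0721) and with loess offsets, where its log2 fold change fell from 0.304 (SE 0.059) to 0.189 (SE 0.055, adjusted p = 0.206). On chromosome 16, Vps26c and Mir99ahg lost it without KO replicate 1 (0.0913 and 0.209). Dscam lost it without WT replicates 3 or 4 or KO replicates 1 or 3 (0.0588 to 0.128), and Bach1 without WT replicates 1, 2 or 3 or KO replicates 1 or 3 (0.0585 to 0.181). The peak from 77643867 lost it without WT replicate 1 or KO replicates 1 or 2 (0.0919 to 0.177), and the peak from 78200338 without KO replicate 3 (0.0538). The remaining peak, Gbe1, lost its call with limma-voom alone (0.0915). Limma-voom also left Mir99ahg (0.0999), the peak from 77643867 (0.145) and Bach1 (0.199) uncalled. With halved counts thinned to 1 depth, Atp6v1d (0.0501) and Galnt6 (0.0784) were not called. With the replicate number as a block, 9 of the 21 lost the call (0.0774 to 0.139). With loess offsets, the peak on chromosome 18 from 79256982 had a log2 fold change of 0.388 (SE 0.093, adjusted p = 0.0673), against 0.464 (SE 0.095).

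Over all tested peaks the share called was 0.087%, so few calls were to be expected in any list. In the effector Treg list, 1 of 239 peaks at 36 genes was called, the lower Bhlhe40 peak. Of its peaks 133 had a fold change below 0, and the median log2 fold change was -0.044 (camera adjusted p = 0.71, fry adjusted p = 0.0535). Adjusted over the list alone, 2 of its peaks passed, Bhlhe40 and a peak 15161 bp from Hopx, a homeodomain cofactor (chromosome 5, 77130284 to 77130784). The Hopx peak had 98.8 ± 16.2 CPM in WT and 65.3 ± 6.19 in KO (log2 fold change -0.57, adjusted p = 0.071 over all peaks). In the core Treg list none of 175 peaks at 18 genes was called (camera adjusted p = 0.935). Its smallest p was at a peak within Ikzf2, which encodes Helios (chromosome 1, 69681078 to 69681335, log2 fold change -1.02, adjusted p = 0.277). In the list of naive and central Treg genes none of 316 peaks was called (camera adjusted p = 0.935). Its smallest p was 27223 bp from S1pr1, a receptor of lymphocyte egress (chromosome 3, 115682540 to 115683210, log2 fold change 0.40, adjusted p = 0.237). In the list of T cell receptor, NF-kB and AP-1 response genes none of 250 peaks was called over all peaks, and 1 passed when adjusted over the list alone. That peak lay on chromosome 16 from 55714872 to 55715229, 96146 bp from Nfkbiz, with 2.73 ± 0.549 CPM in WT and 11.7 ± 3.82 in KO (log2 fold change 2.0, adjusted p = 0.0548). In the list of helper lineage genes and cytokines none of 78 peaks was called. Its smallest p was within Il18r1 (chromosome 1, 40475668 to 40476082, log2 fold change 0.64, adjusted p = 0.236).

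At the peak with the highest mean count of each of 10 genes fixed beforehand, no call was made. The log2 fold change was 0.17 at Foxp3 (X chromosome, 7583850 to 7584440, SE 0.14, adjusted p = 0.754), -0.03 at Il2ra (SE 0.16), -0.02 at Ctla4 (SE 0.14), -0.21 at Ikzf2 (SE 0.11) and 0.11 at Batf (SE 0.20). It was -0.45 at the peak 16216 bp from Tcf7 (chromosome 11, 52299599 to 52300073, SE 0.14, adjusted p = 0.251), a regulator of resting T cells, and -0.22 at the peak 8912 bp from Klrg1 (SE 0.21). At Tigit and Prdm1, genes of effector Treg cells, it was 0.24 (SE 0.11, adjusted p = 0.482) and 0.31 (SE 0.14, adjusted p = 0.461). The groups did not overlap at 4 of these 10 peaks, higher in KO at Tigit and Prdm1 and lower at Ikzf2 and Tcf7. Of all tested peaks 9.36% did not overlap, where chance gives 5.71%. The 10 are the most abundant peaks of their genes, and whether 4 is more than abundant peaks give was not tested. The value was -0.22 (SE 0.20, adjusted p = 0.787) at Tfeb, a regulator of lysosomal genes, and no tested peak was assigned to Atf4. None of these 10 was called in any alternative that gave a value.

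Of the organelle and metabolic lists, the lysosome and autophagy list had 1 called peak among 128 at 60 genes. It lay at an end of Atp6v1d (chromosome 12, 78861426 to 78862169) and rose from 89.0 ± 4.34 to 130 ± 14.2 CPM (log2 fold change 0.54, SE 0.11, adjusted p = 0.0154). Adjusted over the list alone, a peak at an end of Atp6v1b2, another subunit of that pump, passed too (chromosome 8, 69088485 to 69088900, 21.3 ± 7.59 to 38.7 ± 5.98, log2 fold change 0.88, adjusted p = 0.08 over all peaks, so not called there). The list as a whole had 65 peaks above 0 and a median of 0.012 (camera adjusted p = 0.935). With loess offsets the Atp6v1d call was lost by a small margin, at a log2 fold change of 0.476 (SE 0.111, adjusted p = 0.0624), less than 1 SE below its value of 0.541. It was also lost with the replicate block, with thinned counts, and without WT replicates 3 or 4 or KO replicates 2 or 3 (adjusted p from 0.0695 to 0.191 without 1 library). In the list of mitochondrial dynamics and cristae, which holds Opa1, none of 41 peaks was called and 26 were above 0, with a median log2 fold change of 0.063 (camera adjusted p = 0.353, fry adjusted p = 0.0481). Its smallest p was at an end of Mief2, an adaptor of mitochondrial fission (log2 fold change 0.47, adjusted p = 0.367). None of 95 peaks of oxidative phosphorylation genes was called and 50 were above 0. In the integrated stress response list none of 104 was called and 61 were above 0. Their smallest p values were within Ndufa10 (log2 fold change 1.43, adjusted p = 0.268) and near Aldh18a1 (0.56, adjusted p = 0.212).

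No called peak fell in the lists of glycolysis and hypoxia (101 peaks, 44 above 0), mTOR and cholesterol synthesis (64, 35 above 0), cell cycle (110, 63 above 0), apoptosis and p53 (134, 68 above 0) or interferon response (69, 36 above 0). Their peaks with the smallest p were at Ankrd37, a hypoxia-induced gene (log2 fold change -0.36), Rheb, an activator of mTOR (0.33), Birc5, the survivin gene (0.81), Pmaip1, a p53 target (0.98, 5860 bp outside the gene), and Gbp7 (0.40). Their adjusted p values were 0.197, 0.273, 0.262, 0.268 and 0.365. Of the 18 lists, camera called none with its preset correlation or an estimated one, and 1, that of mitochondrial dynamics, had an unadjusted p under 0.05. Fry, which asks only whether a list's peaks move one way on balance, called 2, mitochondrial dynamics and cell cycle (adjusted p = 0.0147), both higher. The median and the camera direction differed in sign for the helper lineage, receptor response and lysosome lists. The median and the mean did so for the apoptosis, interferon, lysosome, naive Treg and oxidative phosphorylation lists. With loess offsets the medians of the apoptosis, interferon, lysosome and mTOR lists lay below 0.

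**Figure D4:**
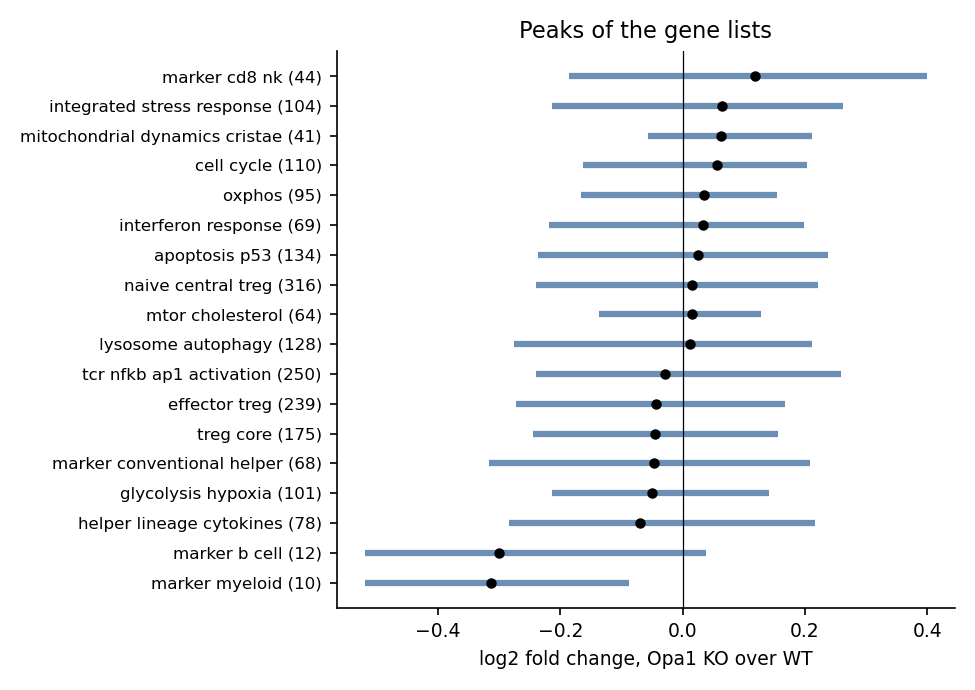
Median (point) and range between the quartiles (bar) of the log2 fold change, Opa1 KO over WT (x axis), of the tested peaks of each of 18 gene lists (y axis, number of peaks in brackets). The median was -0.044 in the effector Treg list and 0.063 in the mitochondrial dynamics list, and the lowest medians, -0.301 and -0.313, were those of the B cell and myeloid marker lists, with 12 and 10 peaks.

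Markers of other cells that the sort might hold gave no call in camera. The B cell list had 4 of 12 peaks above 0 (median -0.301, adjusted p = 0.602), with the smallest p near Cd22 (log2 fold change -0.86, adjusted p = 0.417). The myeloid list had 2 of 10 above 0 (median -0.313, adjusted p = 0.602), with the smallest p near Tyrobp (0.47, adjusted p = 0.372). The list of CD8 T and NK cells had 24 of 44 peaks above 0 (median 0.119, adjusted p = 0.71), with the smallest p near Runx3 (0.48, adjusted p = 0.423). That of conventional helper T cells had 28 of 68 above 0 (median -0.047, adjusted p = 0.935), with the smallest p within Dpp4 (0.52, adjusted p = 0.264).

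Called peaks lay at gene ends less often than other peaks in edgeR's test on all 7 libraries. Peaks within 1 kb of either end of a protein-coding gene made up 3 of the 33 called peaks, 9.1%, against 28.2% of the peaks not called (Fisher's exact test, two-sided, p = 0.0115, peaks not being independent replicates). All 3 were higher, those at Atp6v1d, Atm and Trim30c (whose counts are uncertain where reads map to its close paralogs), and higher and lower calls did not differ in this share (Fisher's exact p = 0.233). With chromosome 16 left out the share among called peaks was 21.4% and no longer differed (Fisher's exact p = 0.769). It was 29.1% with DESeq2, 25.5% with limma-voom and 16.2% with total counts alone, none of them past the test. Without WT replicates 2 or 3 or any 1 KO library the test was not passed either, with shares from 6.2% to 16.3%. Gene-end peaks held 46.6% ± 0.31 of the counts in WT and 47.6% ± 0.30 in KO (SD, n = 3), a difference that an exact two-sided permutation test over the 7 libraries did not call (p = 0.0571, where 0.0286 is the smallest possible; with WT replicates 2 and 3 summed it was 0.1, the smallest that 3 against 3 can give).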

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

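Apart from the search for outlying libraries, the tests in this part were chosen only after the results were seen. Among 53 values tested for a WT library far from the other 3, 2 stood out, where chance alone gives about 1 in 20. WT replicate 2 had a score of -77.9 on the second principal component of the tested peaks, which carried 19.2% of the variance, against 21.4 to 29.4 in the other WT libraries. It also had the highest value at the peak 27223 bp from S1pr1, 99.51 CPM against 72.18 to 74.82. Without this library 43 peaks were called, against 33 with it. It was also the library with the lowest total count, 1534394. Whether its low depth set it apart was not tested, and the score does not show whether it is a separate sample from WT replicate 3 (29.4).

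The genotypes separated on the first principal component (21.8% of the variance), with WT scores from -32.9 to -28.1 and KO scores from 17 to 57.3. Of the 35 ways to split the 7 libraries into 4 and 3, only the real one, 1 of 35, gave as many as 33 called peaks, and the highest other split gave 10. Outside chromosome 16 the real split gave 20 and the highest other 5, again 1 of 35 splits. An unadjusted p under 0.05 was reached by 3603 peaks in the real split and by 3218 in the highest other, also 1 of 35. If the 7 libraries are separate samples, chance assignment is excluded at 0.05 for these counts. With WT replicates 2 and 3 summed, 42 peaks were called, 28 of them outside chromosome 16, and the highest other split gave 0 for both. An unadjusted p under 0.05 was then reached by 3615 peaks, and by 1962 in the highest other split. The 10 splits into 3 and 3, of which 1 gave as many, are too few for a share under 0.05.

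Called peaks gathered on chromosome 16, the chromosome of Opa1, with 13 of 33 against 1.37 expected (exact hypergeometric p = 2.8e-10), which argues against chance placement. Counted as windows of 1 Mb, so that neighbouring peaks count once, 8 of the 24 windows with a called peak lay there, against 0.87 expected (exact hypergeometric p = 9.5e-07). A gain or loss of a copy of the distal part is argued against by the median log2 fold change of 0.043 over the 908 tested peaks beyond 40 Mb. The share of peaks with an unadjusted p under 0.01 gave no sign of a block of foreign DNA centred on the floxed locus. It was 0.96% within 10 Mb of Opa1 against 2.67% outside chromosome 16. The share cannot exclude such a block, since how far foreign DNA would raise it is not known. Between 80 and 90 Mb, inside the span of the called peaks, it was 2.9%. DNA of another mouse strain elsewhere on this chromosome in the KO donor line and an effect of Opa1 loss on these sites cannot be told apart. Either could raise the share beyond 40 Mb, which was 7.27%, and genotype and any linked DNA go together in the 7 libraries.

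Log2 fold changes rose with the abundance of a peak, from a median of -0.111 in the least abundant 20% of the tested peaks to 0.061 in the most abundant 20%, and with loess offsets the medians of the 5 such classes lay between 0.002 and 0.026. Unequal depth is argued against as the cause, since the KO minus WT difference of the slopes per library was 0.0394 at full depth and 0.0425 after thinning all libraries to 1 depth. The exact permutation p over the 7 libraries was 0.0571 at full depth and 0.0286, the smallest possible, after thinning. With WT replicates 2 and 3 as 1 sample it was 0.1, the smallest that 3 against 3 can give, for both. After thinning the slopes ran from 0.0182 to 0.0287 in KO and from -0.0233 to -0.0081 in WT. A difference in signal against background between the libraries and an effect of genotype cannot be told apart. The lowest slope of a KO library, 0.0088, lay above the highest of a WT library, 0.002, at full depth. The low medians of the B cell and myeloid marker lists were nearer 0 with loess offsets, -0.181 and -0.237.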

How the results depend on the processing

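At this depth and number of libraries the simulated test recovered 10.4% of peaks changed 1.5-fold. The number of called peaks, 33 (18 higher, 15 lower), rose to 60 (35 lower) with a mean count of at least 20, to 55 with DESeq2 (29 higher, 26 lower), which left 19176 peaks without an adjusted p, and to 55 with limma-voom (35 higher). With counts halved it was 82 (35 higher, 47 lower). With halved counts thinned to 1 depth there were 26, with 10 higher. With chromosome 16 left out it was 14 (9 higher, 5 lower), 20 having been called outside it with all chromosomes. Total counts alone gave 23 lower and loess offsets 24 lower, and 29 and 24 of the calls were shared with the 33. The threshold of 0.01 left 19 (9 higher) and that of 0.1 gave 88 (45 higher, 43 lower). With WT replicates 2 and 3 summed there were 42, of which 30 were shared. The cause was not tested. Leaving out 1 library gave 15 (without KO replicate 1) to 43 (without WT replicate 2) called peaks, 7 to 25 higher and 7 to 18 lower, and 16 without KO replicate 3 and 18 without WT replicate 1.

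Same-numbered libraries deviated from their group means with correlations of 0.011, -0.012 and 0.004, and differently numbered ones with -0.038 to 0.029. Libraries of a genotype differed little beyond sampling noise (chi-square per degree of freedom 1.004 to 1.08). The correlations could therefore neither show nor exclude that a replicate number pairs libraries. With the replicate number as a block 13 peaks were called, 5 higher and 8 lower, all among the 33, and with peak counts summed per gene 22 genes were called, against 45 without the block. No KO library deviated most like the WT library of its own number.

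The share of gene-end peaks among called peaks, 9.1%, was below that of other peaks in each setting but DESeq2, where it was 29.1%. The test was not passed with total counts alone (16.2%), limma-voom (25.5%) or chromosome 16 left out (21.4%), and the share ran from 5.6% to 16.3% with 1 library left out. The cause was not tested. No list was called by camera in any setting, and fry, run without loess offsets, called 2 lists, both higher.

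No called named peak changed sign in any alternative. One named peak that was not called, near Nfkbiz, was called in 1 alternative, loess offsets. Motif tests, GC offsets, GC offsets with the replicate block and promoter-based settings were not run, since they need the genome sequence or strand, and DESeq2 gave no list tests.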

Other observations

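The tests in this part were chosen after the data had been seen, and the outcome of the V-ATPase test and of the splits of the gene sums over 7 libraries was predicted before it was known. Counts of all peaks assigned to a gene, including peaks that the filter had removed, were summed. Of 12575 genes tested, edgeR called 45, 14 higher and 31 lower in KO. On chromosome 16 lay 4 of them, against 1.52 expected (hypergeometric test, adjusted p = 0.68 over 21 chromosomes). On chromosome 7 lay 12, with 4 higher and 8 lower, against 3.46 expected (adjusted p = 0.0022). These 12 included neighbouring paralogs, whose counts are uncertain where reads map to more than 1 copy: Trim5 (log2 fold change -0.632), Trim12a (-0.577) and Trim30d (-0.966) were lower and Trim30c (0.877) higher. Trim30d lost its call with loess offsets (adjusted p = 0.0836). Of the single called peaks, 2 of 33 lay on chromosome 7, and no explanation was tested. Mpp7, summed over 6 peaks, had the smallest p, as it had among the single peaks outside chromosome 16 (304.9 ± 1.5 CPM in WT, 197.6 ± 18 in KO, log2 fold change -0.63, adjusted p = 6.85e-10). With WT replicates 2 and 3 averaged, this WT SD can be narrower than the spread of the single WT libraries. Other lower genes included Dscam (-0.94), Csrnp3 (-0.94), Akap6, a kinase anchoring protein (-0.63), Pttg1, the securin gene (-0.40), and Apobec3, a restriction factor of retroviruses (-1.86). Higher genes included Atp8a2, a lipid flippase (0.47), Atm, a kinase of the DNA damage response (0.44), and Cd200r3 (0.31). Bhlhe40, summed over 14 peaks, had a smaller fold than at its called peak (-0.30, SE 0.073, adjusted p = 0.0318). It lost the call without WT replicates 1 or 4 (adjusted p = 0.0765 and 0.126) and without KO replicates 1 or 3 (0.273 and 0.336). With all libraries and the replicate number as a block the Bhlhe40 sum was not called either (adjusted p = 0.126).

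No gene sum was called for Foxp3 (0.15, adjusted p = 0.759), Il2ra (0.022), Ctla4 (0.024), Ikzf2 (-0.027), Tcf7 (-0.15), Klrg1 (-0.26), Tigit (0.072), Prdm1 (0.18, adjusted p = 0.335), Batf (-0.12) or Tfeb (-0.30, adjusted p = 0.453). Of the 35 splits of the libraries, only the real one, 1 of 35, gave as many called genes as the 45, and the highest other gave 19, which excludes chance assignment at 0.05 if the 7 libraries are separate samples. With WT replicates 2 and 3 summed 53 genes were called and the highest other split gave 0, and 10 splits, of which 1 gave as many, are too few for a share under 0.05. The count fell to 10 without KO replicate 1, 11 without KO replicate 3, 17 without WT replicate 3, 20 without WT replicate 1 and 24 without WT replicate 4. With loess offsets 41 genes were called, 34 of them in both.

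Peaks of a pair of V-ATPase subunit genes, Atp6v1d and Atp6v1b2, were higher in KO when adjusted over the lysosome list alone; over all peaks Atp6v1d was called and Atp6v1b2 was not (adjusted p = 0.08). The hypothesis that the other V-ATPase genes moved with them, suggested by this pair, was tested on the 52 tested peaks of 19 other genes. Of these peaks 26 were above 0, the median log2 fold change was 0.003 and camera gave p = 0.924 (a test across peaks, not an exact one), which leaves the hypothesis without support and does not exclude a small shift.

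The scaffold JH584304.1 held a larger share of the counts in each KO library (0.258% ± 0.01, SD, n = 3) than in each WT library (0.216% ± 0.009, n = 3; exact two-sided permutation over 7 libraries p = 0.0286, the smallest possible). With WT replicates 2 and 3 summed the p was 0.1, the smallest that 3 against 3 can give. Of its 24 tested peaks 20 had a fold change above 0. Of the 3 called, 1 was lower (31482 to 31809, log2 fold change -0.875, adjusted p = 0.0418). The peak from 58657 lost its call with loess offsets (log2 fold change 0.19, adjusted p = 0.206).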
